A study of Homo sapiens with 13 samples.

How the data were processed

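RNA of 13 libraries of cells labelled TE11, in 4 groups, was measured by sequencing of total RNA with a directional kit (NEBNext Ultra II), per the labels' protocols. The authors deposited 1 table of raw read counts per gene and library, with human gene symbols. The aligner, the counting tool, the annotation and whether the counting used strand are not given in the sources used here. The submitters' processing notes name DESeq, with no version and no role, and the genome build GRCm38, a mouse build, beside human symbols, so no genomic coordinates are printed. The counts were whole numbers whose totals ran from 17834539 to 23679833, and 20102 of 60591 genes had no count in any library. Groups and replicate numbers were taken from the labels, and each column of the table matched 1 library.

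Genes with low counts were removed with filterByExpr of edgeR, which left 19514 genes and at least 99.84% of the counts of each library. Libraries were scaled by TMM, and 1 quasi-likelihood model of edgeR 4.0.16 (R 4.3.3) with a mean per group was fitted to all 13 libraries, so that the groups shared 1 estimate of the spread. Of 6 comparisons, 3 set a treatment against vehicle, 1 each set the combination against 5-FU and against chloroquine, and 1 was the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. CPM are scaled by TMM. Genes beyond both single drugs were those called in the combination against each of them in the same direction, and the effects of each drug with and without the other were correlated across genes.

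The 29 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists within each comparison. They were p53 target genes, apoptosis machinery, G1/S and DNA replication, G2/M and mitosis, DNA repair, pyrimidine, folate and 5-FU metabolism, histones, lysosome, V-ATPase, autophagy, cholesterol synthesis and uptake, ATF4 and the integrated stress response, endoplasmic reticulum chaperones, NRF2 and antioxidant genes, heat shock, cytosolic ribosomal proteins, ribosome biogenesis, snoRNA host genes and nuclear long noncoding RNAs, interferon response, NF-kB and cytokines, squamous differentiation, basal squamous epithelium, mesenchymal state, glycolysis and hypoxia, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, and fibroblast, leukocyte and endothelial markers. Named genes were, per comparison, the 6 called genes with the largest and the 6 with the smallest log2 fold change (4 each for the interaction) among symbols without clone-style names, with a mean log2 CPM of at least 1 and no overlap between the libraries compared. To these were added up to 2 called members with the largest rise and fall of each list with at least 3 called members, and CDKN1A, MDM2, BBC3, BAX, GDF15, TYMS, SQSTM1, MAP1LC3B and HMGCS1 whatever their result. Other genes of the rule are not reported here. The text gives those that describe the lists and summarises the rest, and says where a gene was chosen in another way. The comparisons, the model, the lists, the rule for named genes and the alternatives other than those on the kind of library and the block in 5-FU and the combination alone were fixed before the data were examined.

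Libraries were divided into 2 kinds after the data were examined, by the sign of the first component of their residuals within groups, which held 61.6% of the residual variance. Residuals sum to 0 in a group, so this sign puts both kinds in each group. The component used all tested genes, COL1A2 and other tissue genes among them. It was oriented by the fibroblast list, which holds COL1A2. Counts of these genes are therefore not independent of the kinds. The sign follows the main axis of the same values, so the term takes up residual spread by construction. Each result was recomputed with a term for this kind and in the 8 and the 5 libraries alone. In the 8 libraries chloroquine has 1 library, and in the 5 libraries vehicle, 5-FU and the combination have 1 each and 1 residual degree of freedom remains, so lone libraries are assumed to vary like the others. Gene types came from GENCODE release 29, matched by symbol for 18760 of the tested genes. Other alternatives were size factors of DESeq2 (RLE), library size only, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at 10 CPM in 3 libraries, only the groups compared, the replicate number as a block (also in 5-FU and the combination alone), an absolute log2 fold change of at least 1, and leaving out each library. Residuals of same-numbered libraries correlated above 0.1 in all 3 pairs only between 5-FU and the combination (0.341, 0.743 and 0.339), so there the numbers were taken to pair the libraries. Nothing in the labels says what a number shares, and replicate 2 of both groups is the one with transcripts of other tissues. Pairs of libraries of 1 group differed beyond counting noise, with a chi-square per gene of 1.54 to 18.8, so each was kept as a replicate. The lowest value was that of chloroquine 1 and 2, the only pair of 1 group among the 5 libraries. Calls in the 5 libraries thus assume that the other groups varied as little.

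The model was tested on simulated data drawn from the means and totals of these libraries. Each gene was drawn on its own. Spread common to many genes, such as the component with 61.6% of the residual variance, was left out, so the false calls and list tests below do not cover it. For chloroquine against vehicle, 36 of 67 genes changed by 1.5 times, 45 of 67 changed by 2 times and 56 of 66 changed by 4 times were recovered, with 5 false calls in 19027 genes. For the combination against 5-FU, 41 of 67 genes changed by 1.5 times, 48 of 67 changed by 2 times and 57 of 66 changed by 4 times were recovered, with 17 false calls in 19044 genes, so that about 1 in 10 calls were false there. For the interaction, 24 of 67 genes changed by 1.5 times, 47 of 67 changed by 2 times and 45 of 66 changed by 4 times were recovered, with 6 false calls in 19050 genes. The other comparisons had 2 to 8 false calls. A simulated list of 20 raised genes had a camera p of 4.74e-66 and an unchanged one a camera p of 0.315 in that chloroquine comparison. Fewer of the genes under 1 CPM were recovered, 7 of 39 against 130 of 161 of the others for chloroquine against vehicle and 3 of 40 against 113 of 160 for the interaction.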

Results

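The libraries came from TE11, a human esophageal squamous cell carcinoma line per the labels, kept for 48 h in 0.1% DMSO (vehicle, n = 4), 10 µM chloroquine (n = 3), 25 µM 5-fluorouracil (5-FU, n = 3) or both drugs together (combination, n = 3). Chloroquine is a weak base that accumulates in lysosomes and blocks late steps of autophagy, and 5-FU is a pyrimidine analogue that inhibits thymidylate synthase and is incorporated into RNA and DNA. The title of the series concerns chloroquine as a sensitiser to 5-FU through p53 signalling. Total counts were 19679429, 18927168, 22089671 and 20504722 in vehicle replicates 1 to 4 and 21828931, 22191857 and 17834539 in chloroquine. They were 19507898, 20250837 and 23679833 in 5-FU and 22411504, 21327600 and 21665613 in the combination. Of 60591 genes, 19514 passed the filter on low counts. Values after ± are the SE of a log2 fold change or the SD between libraries of counts scaled to a common library size (CPM), and every comparison used these group sizes. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples, which could be technical.

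Markers of squamous epithelium were near the limit of detection in the libraries labelled TE11. Of 29 squamous differentiation genes, 23 had at most 10 counts in each of the 8 libraries described next, as did 4 of 17 basal squamous genes. The libraries were also of 2 kinds that cross the treatments. Vehicle 4, chloroquine 1 and 2, 5-FU 2 and combination 2 held transcripts of other tissues, such as 153 to 741 counts of the collagen gene COL1A2, against 1 to 7 in the other 8. Chloroquine therefore had 2 such libraries of 3 and each other group had 1. These libraries were not alike. HBB had 0 counts in 5-FU 2 and combination 2 against 88 to 203 in vehicle 4 and chloroquine 1 and 2. AMY1A had 2 counts in combination 2, and whether RNA or reads of other samples entered that library stays undecided. Counts of changed genes from a fit with a term for the kind of library are given beside the pooled ones. Mitochondrial transcripts took 1.72 ± 0.12% of counts in vehicle, 2.60 ± 0.35% with chloroquine, 3.23 ± 0.38% with 5-FU and 2.76 ± 0.13% in the combination.

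**Figure D1:**
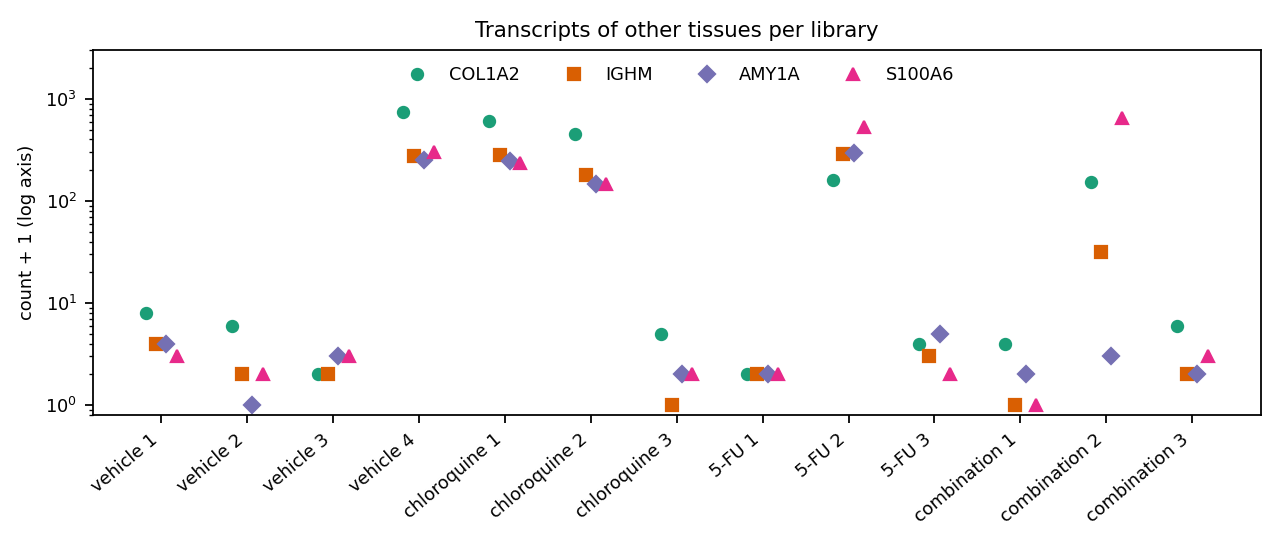
Counts plus 1 (log axis) of COL1A2, IGHM, AMY1A and S100A6 in each of the 13 libraries, 1 point per gene and library. COL1A2 lay at 153 to 741 counts in vehicle 4, chloroquine 1 and 2, 5-FU 2 and combination 2 and at 1 to 7 in the rest. AMY1A lay at 146 to 292 counts in vehicle 4, chloroquine 1 and 2 and 5-FU 2 but at 2 in combination 2.

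Chloroquine alone lowered heat shock and ribosome biogenesis transcripts and raised p53 targets. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 31.7 ± 1.02 to 70.5 ± 4.99 CPM, a log2 fold change of 1.15 ± 0.0695 (edgeR adjusted p = 5.45e-08). HSPA1A and HSPA1B, near-identical copies of the inducible HSP70 gene whose reads cannot be split with certainty, both fell (log2 -1.96 ± 0.0686 and -1.97 ± 0.0573). The largest rises of the rule were in ONECUT3 (4.51 ± 0.262), KRTAP19-1 (2.89 ± 0.0702) and SORCS1 (2.42 ± 0.145), and falls included SELENOW (-1.79 ± 0.0816) and PIR (-1.57 ± 0.125). In all, 7682 genes changed, 3952 upward and 3730 downward, and 858 of the rises but 104 of the falls reached an absolute log2 fold change of 1.

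In the p53 target list with chloroquine alone, 21 of 39 tested members rose, 1 fell and 17 did not pass, with a median log2 fold change of 0.25 (same counts adjusted over the list alone, camera adjusted p = 3.45e-05). TP53INP1 rose by 1.11 ± 0.0936 and BBC3, encoding the pro-apoptotic protein PUMA, by 0.71 ± 0.112. TP53I3 fell (log2 -0.44 ± 0.119, not passing in the 8 or the 5 libraries taken alone). MDM2 (-0.12 ± 0.0722, which passed at -0.21 without chloroquine 3 and at -0.18 in the 5 libraries), BAX (-0.036 ± 0.101, passing at 0.15 in the 5 libraries) and GDF15 (0.68 ± 0.33) did not pass the test. All 12 heat shock genes fell (same counts adjusted over the list alone, camera adjusted p = 7.27e-10). Of the ribosome biogenesis genes, 21 of 25 tested members fell, 0 rose and 4 did not pass (0 up and 22 down adjusted over the list alone, camera adjusted p = 1.96e-07). NPM1, a nucleolar protein, was at -0.52 ± 0.0685. In the ATF4 and integrated stress response list 13 of 20 tested members rose, 3 fell and 4 did not pass (14 up and 4 down adjusted over the list alone, camera adjusted p = 0.000634, adjusted p = 0.138 with an estimated correlation). NUPR1 was at 2.75 ± 0.34 and CHAC1, a glutathione-degrading enzyme, at 1.70 ± 0.131. In the NRF2 list 9 of 16 tested members fell, 1 rose and 6 did not pass (1 up and 10 down adjusted over the list alone, camera adjusted p = 0.000165). HMOX1, heme oxygenase 1, was at -1.04 ± 0.0946. Of the cholesterol genes, 11 of 23 tested members rose, 2 fell and 10 did not pass (12 up and 3 down adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.207 with an estimated correlation). INSIG1, an endoplasmic reticulum brake on SREBP processing, rose by 1.08 ± 0.053, STARD4 by 0.75 ± 0.0776 and HMGCS1, an early enzyme of cholesterol synthesis, by 0.53 ± 0.0575.

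Among lysosomal genes, 13 of 33 tested members rose, 2 fell and 18 did not pass (14 up and 2 down adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.261 with an estimated correlation). GPNMB was at 0.97 ± 0.19, a call lost in the 8 and in the 5 libraries taken alone (0.78 and 0.79). Autophagy genes went both ways: 10 of 33 tested members rose, 4 fell and 19 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.335). The autophagy receptor gene OPTN rose by 0.96 ± 0.0486 and WIPI1 by 0.90 ± 0.108. ATG2A fell (log2 -0.48 ± 0.103), MAP1LC3B was at 0.19 ± 0.0654 and SQSTM1 did not pass the test (-0.085 ± 0.0977). Of the V-ATPase genes, 3 of 16 tested members rose, 2 fell and 11 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.817). In the G2/M list 18 of 30 tested members fell, 2 rose and 10 did not pass (2 up and 19 down adjusted over the list alone, camera adjusted p = 1.96e-07, adjusted p = 0.105 with an estimated correlation), led by the mitotic genes CDC20 (-0.89 ± 0.067) and PLK1 (-0.83 ± 0.0738). The nuclear-encoded respiratory chain and the mitochondrially encoded mRNAs moved apart. Of the former, 15 of 24 tested members fell, 0 rose and 9 did not pass (0 up and 18 down adjusted over the list alone, camera adjusted p = 1.61e-05, adjusted p = 0.207 with an estimated correlation). Of the latter, 11 of 13 tested members rose, 0 fell and 2 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.000165, adjusted p = 0.407 with an estimated correlation). CYC1 was at -0.58 ± 0.0941 and MT-ND2 at 1.12 ± 0.13. Of the snoRNA host and nuclear long noncoding RNA list, 8 of 12 tested members rose, 1 fell and 3 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.00507, adjusted p = 0.267 with an estimated correlation). NEAT1 was at 0.86 ± 0.0611. Of the ribosomal protein genes, 16 of 75 tested members fell, 4 rose and 55 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.606 with an estimated correlation). Their median of -0.088 became 0.0089 with library size only, and the call was lost there, with a filter at 10 CPM, in the 5 libraries and without vehicle 1 (camera adjusted p = 0.101, 0.352, 0.519 and 0.0876). In the G1/S list 9 of 31 tested members fell, 2 rose and 20 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.0225, adjusted p = 0.233 with an estimated correlation). In the NF-kB and cytokine list 3 of 9 tested members rose, 0 fell and 6 did not pass (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.0329, adjusted p = 0.138 with an estimated correlation). In the apoptosis list 6 of 26 tested members rose, 4 fell and 16 did not pass (7 up and 4 down adjusted over the list alone, camera adjusted p = 0.477). With the kind term the G1/S (camera adjusted p = 0.0761) and NF-kB (camera adjusted p = 0.0684) calls were lost, as they were with library size only, a filter at 10 CPM and in the 8 or the 5 libraries. TYMS, the 5-FU target thymidylate synthase, was called at -0.15 ± 0.0517, a call lost with library size only (-0.051), a filter at 10 CPM (-0.094) and no filter (-0.15), in the 8 libraries (-0.22) and without any single vehicle library or chloroquine 1 or 3 (-0.16 to -0.13). That of MAP1LC3B was lost with RLE (0.17), in the 8 libraries (0.15) and without vehicle 2, 3 or 4, any chloroquine library, 5-FU 3 or combination 1 or 2 (0.16 to 0.20). The kind term gave 8328 changed genes (7261 of the 7682 kept with their direction), the 8 libraries 4396 with 1 chloroquine library, and the 5 libraries 7880. With library size only, which moves the median of all genes by 0.0956, 5435 genes were called up and 2410 down, and with RLE 3712 up and 4047 down.

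5-FU alone raised p53 targets and lowered ribosome biogenesis and heat shock transcripts. GDF15, a secreted stress cytokine and p53 target, rose from 0.413 ± 0.199 to 26.5 ± 3.59 CPM (log2 5.95 ± 0.183, edgeR adjusted p = 1.15e-11) and CDKN1A to 144 ± 13.1 CPM (log2 2.19 ± 0.0684, edgeR adjusted p = 1.27e-11). The transcription factor gene MYC fell (log2 -2.42 ± 0.0761, edgeR adjusted p = 1.34e-11), and so did the cystine transporter gene SLC7A11 (log2 -2.48 ± 0.0844). DDIT3, which encodes the stress factor CHOP, rose by 2.68 ± 0.09 and HMOX1 by 2.50 ± 0.0776. In all, 11759 genes changed, 6003 upward and 5756 downward, and 2142 of the rises but 593 of the falls reached an absolute log2 fold change of 1.

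In the p53 target list 34 of 39 tested members rose, 1 fell and 4 did not pass, with a median of 0.69 (35 up and 1 down adjusted over the list alone, camera adjusted p = 4.97e-11). MDM2, a p53 target that encodes a ubiquitin ligase, rose by 0.47 ± 0.0708, BBC3 by 0.81 ± 0.11 and BAX by 0.41 ± 0.0991. ASCC3 fell (log2 -0.56 ± 0.0814). Further large rises were in ATP6V0D2 (4.92 ± 0.405), ANKRD1 (4.16 ± 0.179) and PLXNB3 (4.03 ± 0.327), and falls in CA2 (-2.50 ± 0.0445), RPL22L1 (-2.50 ± 0.113) and ALDH1L2 (-2.08 ± 0.093). ROR1-AS1 went from 0.0404 ± 0.0523 to 4.19 ± 1.43 CPM. It lies antisense to a gene, and whether the counting used strand is not given in the sources used here, so its identity is uncertain. Of the cytosolic ribosomal protein genes, many of which have near-identical pseudogenes and are uncertain one by one, 69 of 75 tested members fell, 3 rose and 3 did not pass (3 up and 70 down adjusted over the list alone, camera adjusted p = 3.22e-15, adjusted p = 0.199 with an estimated correlation). RPL3 was at -1.41 ± 0.0583. Processed pseudogenes took 6.05 ± 0.053% of counts in vehicle and 4.33 ± 0.086% with 5-FU. Of the ribosome biogenesis genes, 23 of 25 tested members fell, 1 rose and 1 did not pass (same counts adjusted over the list alone, camera adjusted p = 2.5e-08). UTP20 was at -1.25 ± 0.0681 and NPM1 at -1.21 ± 0.0701. In the heat shock list 11 of 12 tested members fell, 1 rose and 0 did not pass (same counts adjusted over the list alone, camera adjusted p = 7.95e-05). HSPA1B was at -2.12 ± 0.0577 and HSPB1 the exception at 0.96 ± 0.0959.

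In the glycolysis and hypoxia list 16 of 22 tested members fell, 5 rose and 1 did not pass (5 up and 17 down adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.228 with an estimated correlation). PDK1, pyruvate dehydrogenase kinase 1, was at -1.52 ± 0.0687. Of the cholesterol genes, 13 of 23 tested members fell, 1 rose and 9 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.0058, adjusted p = 0.199 with an estimated correlation). Examples were INSIG1 (-1.21 ± 0.0573) and HMGCS1 (-0.79 ± 0.0601). In the pyrimidine, folate and 5-FU metabolism list 12 of 25 tested members fell, 6 rose and 7 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.16), and the median of -0.16 turned positive with library size only. It passed without the filter on low counts (camera adjusted p = 0.0183). SHMT2, mitochondrial serine hydroxymethyltransferase, fell (log2 -1.64 ± 0.0579) and TYMS rose by 0.28 ± 0.0509. The G2/M list had 18 falls and 4 rises in 30 tested members (4 up and 19 down adjusted over the list alone, camera adjusted p = 0.00132, adjusted p = 0.228 with an estimated correlation). BUB1B was at -0.88 ± 0.0579 and HMMR at -0.89 ± 0.0962. The G1/S list had 17 falls and 5 rises in 31 (same counts adjusted over the list alone, camera adjusted p = 0.0373, adjusted p = 0.228 with an estimated correlation). POLA1, a DNA polymerase subunit, was at -1.33 ± 0.0608. ATF4 list members split: 11 of 20 tested members fell, 6 rose and 3 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.16), and the list passed without the filter on low counts (camera adjusted p = 0.0207). Among the falls were SLC7A11 and PHGDH (-1.51 ± 0.0988) and among the rises DDIT3 and PPP1R15A (1.75 ± 0.0837). Of the endoplasmic reticulum chaperone genes, 10 of 16 tested members fell, 2 rose and 4 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.199 with an estimated correlation). In the NF-kB and cytokine list 7 of 9 tested members rose, 1 fell and 1 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.0147, adjusted p = 0.123 with an estimated correlation). In the interferon list 9 of 17 tested members rose, 2 fell and 6 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.0373, adjusted p = 0.162 with an estimated correlation). Among the NF-kB genes were LIF, an interleukin 6 family cytokine, at 3.44 ± 0.138 and RELB at 2.47 ± 0.141. SQSTM1 rose by 1.09 ± 0.0926, MAP1LC3B by 0.46 ± 0.0649 and GPNMB by 2.26 ± 0.171. Of the autophagy genes, 11 of 33 tested members rose, 10 fell and 12 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.531). Of the lysosomal genes, 16 of 33 tested members rose, 7 fell and 10 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.275). In the nuclear-encoded respiratory chain 13 of 24 tested members fell and 0 rose (same counts adjusted over the list alone, camera adjusted p = 0.00291, adjusted p = 0.327 with an estimated correlation). That call was lost with library size only and a filter at 10 CPM (camera adjusted p = 0.0502 and 0.118). Of the mitochondrially encoded mRNAs, 8 of 13 rose and 0 fell (camera adjusted p = 0.0532), a list that passed without the filter on low counts (camera adjusted p = 0.0253). The calls of the G1/S (median 0.031), cholesterol, chaperone, interferon and NF-kB lists were lost with library size only and with a filter at 10 CPM. Those of the G1/S, chaperone and interferon lists were also lost in the 5 libraries, and that of the G1/S list with the 2 groups alone (camera adjusted p = 0.0525) and without 5-FU 2 (camera adjusted p = 0.0735). The kind term gave 12646 changed genes (11727 kept with their direction), the 8 libraries 11716 and the 5 libraries 10258. Library size only moved the median of all genes by 0.192 and called 8291 up and 3669 down.

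The combination against vehicle held the highest CDKN1A level, 191 ± 8.59 CPM (log2 2.59 ± 0.0685, edgeR adjusted p = 5.92e-12). GDF15 rose by 5.19 ± 0.191, MDM2 by 0.76 ± 0.0705 and BBC3 by 0.99 ± 0.109. In the p53 target list 36 of 39 tested members rose, 1 fell and 2 did not pass, with a median of 0.95 (same counts adjusted over the list alone, camera adjusted p = 1.8e-13). Of the apoptosis genes, 16 of 26 tested members rose, 3 fell and 7 did not pass (17 up and 3 down adjusted over the list alone, camera adjusted p = 0.00779, adjusted p = 0.179 with an estimated correlation). DIABLO, an inhibitor of caspase inhibitors, was at 1.30 ± 0.12 and BAD at 1.23 ± 0.13. Altogether 10801 genes changed, 5489 upward and 5312 downward, of which 1644 rises and 577 falls reached an absolute log2 fold change of 1.

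The largest changes in the combination included OSTN (4.84 ± 0.16), INPP5D (3.96 ± 0.207), SRPK3 (-2.68 ± 0.191) and PRR22 (-2.62 ± 0.18). DDIT3 was at 3.04 ± 0.0891, SLC7A11 at -2.58 ± 0.0853 and HSPA1B at -2.56 ± 0.0594. In the heat shock list 10 of 12 tested members fell, 1 rose and 1 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.000283). In ribosome biogenesis 23 of 25 tested members fell, 0 rose and 2 did not pass (same counts adjusted over the list alone, camera adjusted p = 6e-09). RRP12 was at -1.50 ± 0.0805. In the ribosomal protein list 65 of 75 tested members fell, 1 rose and 9 did not pass (1 up and 66 down adjusted over the list alone, camera adjusted p = 8.16e-12, adjusted p = 0.196 with an estimated correlation). G1/S genes fell in 22 of 31 cases (4 up and 22 down adjusted over the list alone, camera adjusted p = 8.09e-05, adjusted p = 0.0647 with an estimated correlation). G2/M genes fell in 20 of 30 (same counts adjusted over the list alone, camera adjusted p = 2.44e-05, adjusted p = 0.179 with an estimated correlation). KIF20A was at -1.01 ± 0.0593 and PLK1 at -1.01 ± 0.0742. Glycolysis genes fell in 16 of 22 (4 up and 16 down adjusted over the list alone, camera adjusted p = 0.000261, adjusted p = 0.179 with an estimated correlation). VEGFA was at -1.33 ± 0.0834. In the V-ATPase list 10 of 16 tested members rose, 1 fell and 5 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.179 with an estimated correlation). Of the lysosomal genes, 17 of 33 tested members rose, 10 fell and 6 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.298). GPNMB was at 3.65 ± 0.163. Of the autophagy genes, 16 of 33 tested members rose, 12 fell and 5 did not pass (17 up and 12 down adjusted over the list alone, camera adjusted p = 0.278). OPTN was at 1.59 ± 0.0475, SQSTM1 at 0.74 ± 0.0935 and MAP1LC3B at 0.57 ± 0.0648. In the pyrimidine list 14 of 25 tested members fell, 4 rose and 7 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.321 with an estimated correlation), a call lost with a filter at 10 CPM (camera adjusted p = 0.0714) and in the 5 libraries (camera adjusted p = 0.0613). UPP1, uridine phosphorylase 1, was at 1.35 ± 0.103, SHMT2 at -1.88 ± 0.0586 and TYMS at 0.20 ± 0.051. NF-kB genes rose in 5 of 9 cases (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.103 with an estimated correlation). Chaperones fell in 11 of 16 (same counts adjusted over the list alone, camera adjusted p = 0.0253, adjusted p = 0.196 with an estimated correlation), a call lost with library size only, with a filter at 10 CPM and in the 5 libraries (camera adjusted p = 0.0774, 0.168 and 0.111). BAX was at 0.41 ± 0.0991, and HMGCS1 did not pass the test (0.088 ± 0.058) except with library size only (0.24) and with a filter at 10 CPM (0.15). The kind term gave 11749 changed genes (10770 kept with their direction), the 8 libraries 10428 and the 5 libraries 9728. Library size only moved the median of all genes by 0.148 and called 7422 up and 3659 down, and RLE called 5377 up and 5411 down.

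**Figure D2:**
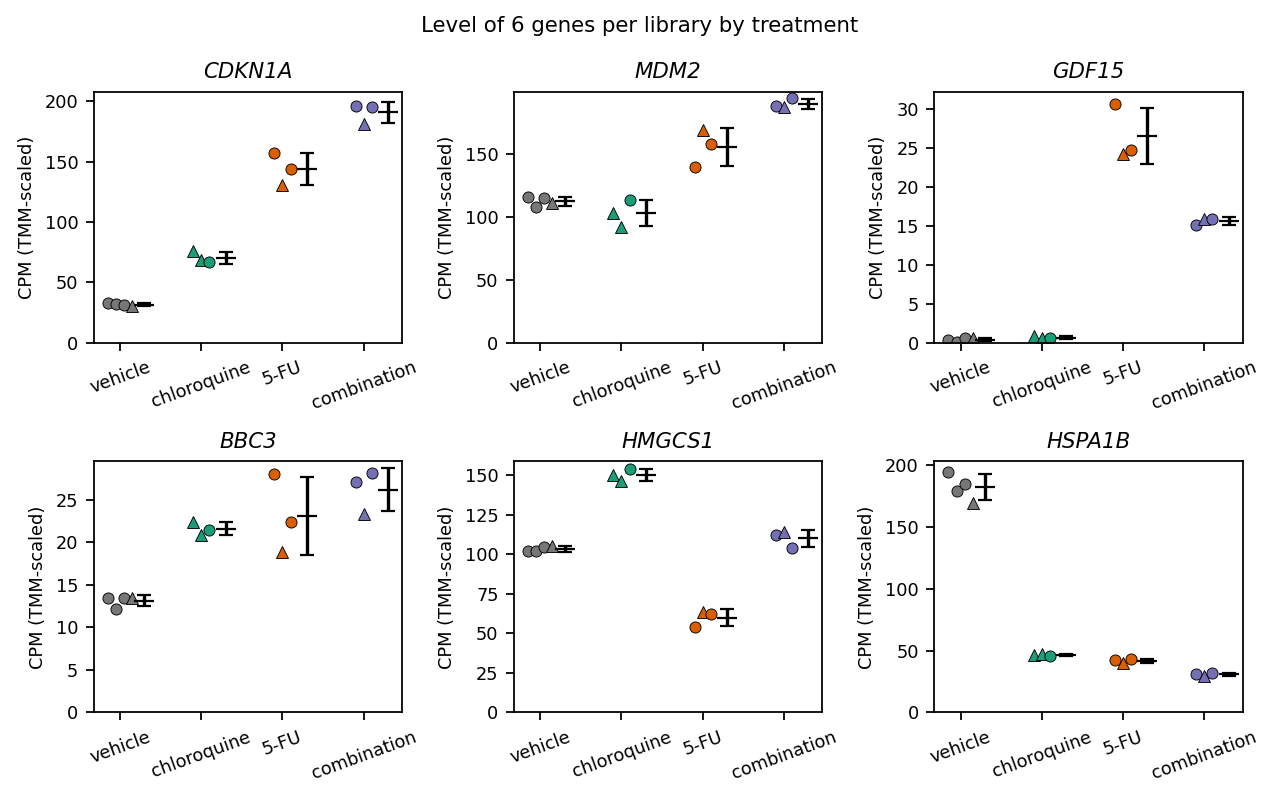
CPM of 6 genes in each library by treatment (circles: 8 libraries without transcripts of other tissues, triangles: 5 with), with bars for the mean and SD of each group. CDKN1A rose from 31.7 ± 1.02 CPM in vehicle to 191 ± 8.59 in the combination, and GDF15 was higher with 5-FU (26.5 ± 3.59) than in the combination (15.6 ± 0.485).

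**Figure D3:**
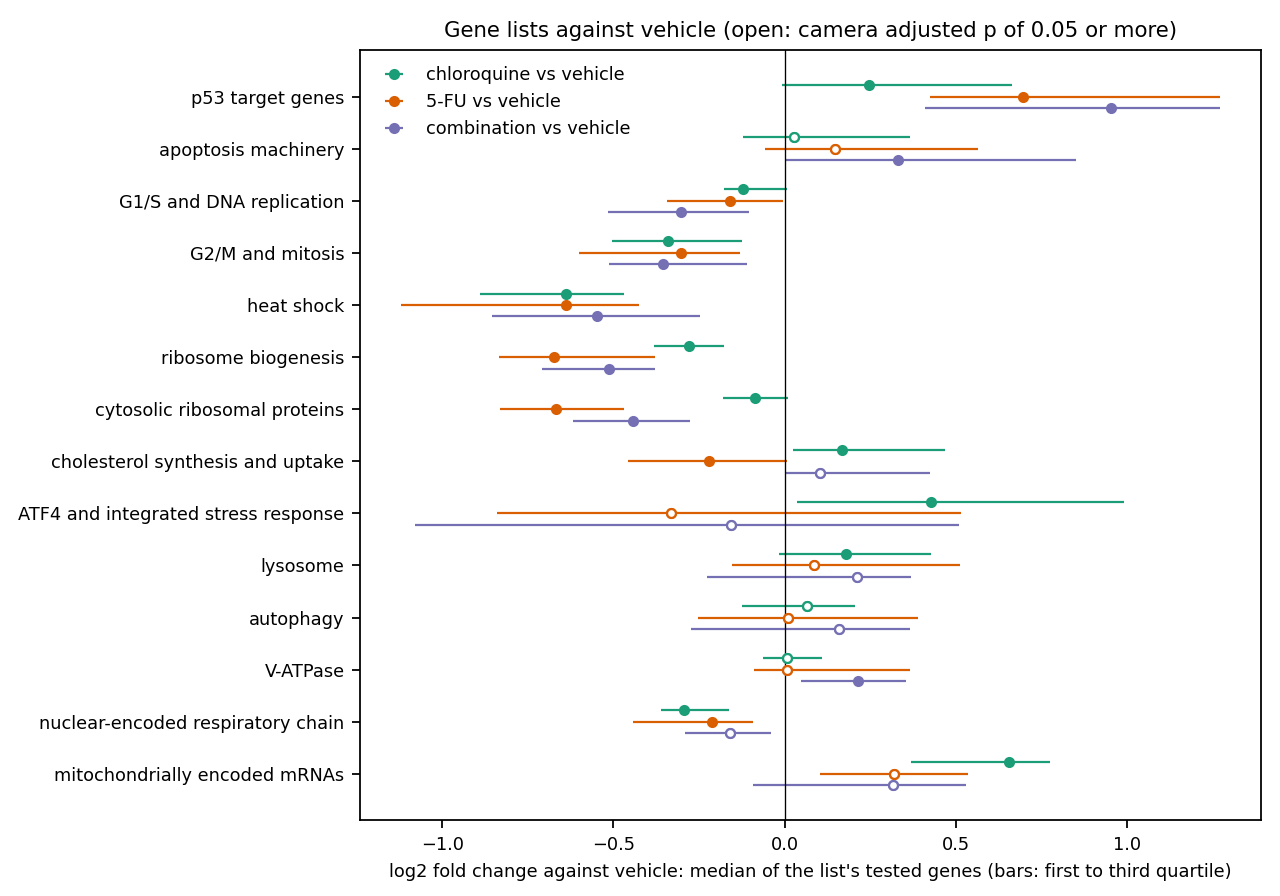
Median log2 fold change against vehicle of the tested genes of 14 lists (points), with bars from the first to the third quartile, for the 3 treatments; open points have a camera adjusted p of 0.05 or more. The p53 targets had medians of 0.25, 0.69 and 0.95. With library size only the median of the ribosomal proteins with chloroquine and of the G1/S list with 5-FU turned positive (0.0089 and 0.031).

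In what chloroquine added to 5-FU, the comparison the title concerns, p53 targets went both ways. CDKN1A was higher in the combination than with 5-FU by 0.41 ± 0.0687 (edgeR adjusted p = 0.00036) and MDM2 by 0.29 ± 0.0753. GDF15 was lower (log2 -0.76 ± 0.123, edgeR adjusted p = 0.000252). In the p53 target list 17 of 39 tested members rose, 9 fell and 13 did not pass, and the list did not pass its test (median 0.18) (19 up and 10 down adjusted over the list alone, camera adjusted p = 0.422). ZMAT3 (0.71 ± 0.0741) and TIGAR (0.67 ± 0.114) rose, PIDD1 (-1.02 ± 0.114) and FDXR (-0.84 ± 0.122) fell. BBC3 (0.18 ± 0.112, passing at 0.34 without 5-FU 1 and at 0.31 in the 5 libraries) and BAX (0.0031 ± 0.105) did not pass the test. Altogether 7517 genes changed, 3937 upward and 3580 downward, but 199 rises and 771 falls reached an absolute log2 fold change of 1. With library size only, which moves the median by -0.0437, 3221 were called up and 4064 down.

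In the cholesterol list 15 of 23 tested members rose, 1 fell and 7 did not pass (same counts adjusted over the list alone, camera adjusted p = 1.73e-06, adjusted p = 0.0835 with an estimated correlation). Examples were INSIG1 (1.68 ± 0.0601), MSMO1 (1.17 ± 0.0886) and HMGCS1 (0.88 ± 0.0632). Of the ribosomal protein genes, 36 of 75 tested members rose, 2 fell and 37 did not pass (39 up and 2 down adjusted over the list alone, camera adjusted p = 8.67e-05, adjusted p = 0.699 with an estimated correlation). In the apoptosis list 9 of 26 tested members rose, 1 fell and 16 did not pass (10 up and 1 down adjusted over the list alone, camera adjusted p = 0.067), and the list passed without the filter on low counts (camera adjusted p = 0.00912). XIAP, a caspase inhibitor, was at 0.82 ± 0.0862. LAMB3, a laminin chain, rose by 1.82 ± 0.241 and GPNMB by 1.39 ± 0.149. Falls included HMOX1 (-1.80 ± 0.081), LIG1 (-1.25 ± 0.0582), FANCA (-0.89 ± 0.0707) and NEAT1 (-1.09 ± 0.0635), of which LIG1 is DNA ligase 1 and FANCA a Fanconi anemia repair gene. EIF4A1 (-2.30 ± 0.126) overlaps readthrough transcripts and is uncertain. Among autophagy genes, 11 of 33 tested members rose, 6 fell and 16 did not pass (11 up and 7 down adjusted over the list alone, camera adjusted p = 0.422). ATG2A was at -1.34 ± 0.109 and the kinase gene ULK1 at -0.90 ± 0.084. SQSTM1 was lower (-0.35 ± 0.0968), a call lost without combination 2 (-0.28), and MAP1LC3B (0.11 ± 0.0692) and TYMS (-0.08 ± 0.0543) did not pass the test. UPP1 rose by 1.01 ± 0.108. In the G1/S list 13 of 31 tested members fell, 4 rose and 14 did not pass (4 up and 14 down adjusted over the list alone, camera adjusted p = 0.053), short of the threshold. It passed under 9 alternatives, with camera adjusted p = 0.0484 (RLE), 0.0232 (library size only), 0.0485 (DESeq2), 0.0494 (limma-voom), 0.0203 (no filter), 0.0213 (filter at 10 CPM), 0.0465 (kind term) and 0.037 and 0.0392 (without 5-FU 1 or 2). The kind term gave 8668 changed genes (7497 kept with their direction), the 8 libraries 7264 and the 5 libraries 6618.

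What 5-FU added to chloroquine was again led by p53 targets. GDF15 rose by 4.51 ± 0.193 and CDKN1A by 1.44 ± 0.0711 (edgeR adjusted p = 2.7e-09), TP53I3 by 1.96 ± 0.113 and MDM2 by 0.88 ± 0.0765. In the list 29 of 39 tested members rose, 2 fell and 8 did not pass (median 0.49) (31 up and 2 down adjusted over the list alone, camera adjusted p = 9.32e-09). Of the glycolysis and hypoxia genes, 16 of 22 tested members fell, 1 rose and 5 did not pass (same counts adjusted over the list alone, camera adjusted p = 7.11e-06, adjusted p = 0.189 with an estimated correlation). VEGFA was at -2.26 ± 0.0859 and PDK1 at -1.87 ± 0.0708. In the ATF4 list 12 of 20 tested members fell, 6 rose and 2 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.00833, adjusted p = 0.295 with an estimated correlation), a call lost with a filter at 10 CPM (camera adjusted p = 0.101). SLC7A11 fell (log2 -3.12 ± 0.0871), CHAC1 fell (log2 -2.14 ± 0.146) and DDIT3 rose by 2.01 ± 0.0896. Ribosomal protein genes fell in 49 of 75 cases (2 up and 52 down adjusted over the list alone, camera adjusted p = 4.23e-08, adjusted p = 0.343 with an estimated correlation). Chaperones fell in 12 of 16 (same counts adjusted over the list alone, camera adjusted p = 0.000968, adjusted p = 0.161 with an estimated correlation). Other large changes were in MAP2 (3.95 ± 0.203), KCNAB3 (-2.92 ± 0.178) and SLC6A9 (-2.85 ± 0.103). TYMS was at 0.35 ± 0.0548, SQSTM1 at 0.83 ± 0.101, MAP1LC3B at 0.38 ± 0.0696, BAX at 0.45 ± 0.107 and HMGCS1 at -0.45 ± 0.0616. BBC3 did not pass the test (0.28 ± 0.113). It passed with RLE (0.29), library size only (0.33), DESeq2 (0.29), no filter (0.28), a filter at 10 CPM (0.29) and the 2 groups alone (0.29). It also passed without combination 2 (0.36) or 5-FU 1 or 2 (0.29 each). In all, 9867 genes changed, 4846 upward and 5021 downward, of which 915 rises and 862 falls reached an absolute log2 fold change of 1. The majority turned with library size only (5534 up and 4379 down, the median moving by 0.0524) and with RLE (4976 up and 4886 down). With the kind term there were 10637 (9686 kept with their direction), the 8 libraries 6812 and the 5 libraries 10513.

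The combination lay beyond both single drugs, past the threshold against each and in the same direction, at 3045 genes, 1479 higher and 1566 lower. CDKN1A, MDM2, GPNMB and LAMB3 were among the higher and LIG1, FANCA, HSPA1A and HSPA1B among the lower genes. Independent lists of the same sizes would share 977.7 and 921.1 genes. Unchanged groups simulated against shared libraries gave 0 in each of 12 simulations. Each gene was drawn there on its own and without a change, so few calls were possible and the 0 tells little about shared libraries. Both comparisons use the same 3 combination libraries, too few to split, so part of the excess may come from them. The kind term gave 1787 higher and 1831 lower genes, and the 8 libraries 2012 in all.

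Whether each drug acted alike with and without the other was asked through the interaction, the log2 effect of chloroquine on top of 5-FU minus that on vehicle. Chloroquine lowered HSPA1A and HSPA1B less on top of 5-FU than on vehicle, a difference of 1.53 ± 0.0831 for HSPA1B (edgeR adjusted p = 2.26e-08). In the list, 11 of 12 heat shock genes had a positive difference (same counts adjusted over the list alone, camera adjusted p = 2.94e-08). On top of 5-FU, chloroquine raised 7 of them and lowered 2, with a median of 0.17 (same counts adjusted over the list alone, camera adjusted p = 0.507). CDKN1A had a difference of -0.75 ± 0.0979 (edgeR adjusted p = 4.76e-05), so that the combination lay below the sum of the single effects although above each of them. GDF15 was at -1.45 ± 0.354, PIDD1 at -1.72 ± 0.159 and BBC3 at -0.53 ± 0.158 (not passing in the 5 libraries, -0.37), while MDM2 lay above the sum (0.41 ± 0.104), a call lost with library size only (0.27). The call of GDF15 was lost in the 8 and in the 5 libraries taken alone (-1.42 and -0.97). In the p53 target list 6 members had a positive and 18 a negative difference (median -0.22) (same counts adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.0865 with an estimated correlation). In all, 7791 genes had an interaction, 4019 positive and 3772 negative, but 185 of the positive and 1621 of the negative differences reached an absolute log2 value of 1. The labels name DMSO for vehicle alone, so a trait of the vehicle libraries would enter the interaction as well.

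Positive differences prevailed in ribosome biogenesis (15 positive, 1 negative of 25) (16 up and 1 down adjusted over the list alone, camera adjusted p = 0.000129, adjusted p = 0.0586 with an estimated correlation), led by NPM1 (0.86 ± 0.0998). The ribosomal protein list had 38 positive and 2 negative differences in 75 genes (43 up and 2 down adjusted over the list alone, camera adjusted p = 2.82e-06, adjusted p = 0.395 with an estimated correlation). The nuclear-encoded respiratory chain had 16 positive and 0 negative differences in 24 genes (19 up and 0 down adjusted over the list alone, camera adjusted p = 1.83e-05, adjusted p = 0.286 with an estimated correlation). G2/M had 15 positive and 3 negative differences in 30 genes (18 up and 3 down adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.301 with an estimated correlation). The cholesterol list had 9 positive and 1 negative differences in 23 genes (10 up and 1 down adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.286 with an estimated correlation). Negative differences prevailed in the mitochondrially encoded mRNAs (10 negative, 0 positive of 13) (0 up and 12 down adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.483 with an estimated correlation). The ATF4 list had 11 negative and 1 positive in 20 genes (same counts adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.301 with an estimated correlation). CHAC1 was at -2.07 ± 0.203. The snoRNA host and nuclear RNA list had 8 negative and 1 positive in 12 genes (same counts adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.393 with an estimated correlation). NEAT1 was at -1.95 ± 0.0881. The lysosome list did not pass its interaction test. With negative medians it passed under the kind term, library size only, no filter, a filter at 10 CPM and without 5-FU 2 (camera adjusted p = 0.0381, 0.0159, 0.0418, 0.00728 and 0.0225). HMGCS1 was at 0.34 ± 0.0855, a call lost with library size only (0.20) and in the 8 libraries (0.32). BAX (0.039 ± 0.146), TYMS (0.067 ± 0.0749), SQSTM1 (-0.27 ± 0.137) and MAP1LC3B (-0.076 ± 0.0953) did not pass the test. MAP1LC3B passed in the 5 libraries (-0.23). SQSTM1 passed with the kind term (-0.34), library size only (-0.41) and a filter at 10 CPM (-0.36), and without 5-FU 2 (-0.35) or combination 3 (-0.37). In the 8 libraries the calls of the mitochondrial mRNAs (camera adjusted p = 0.107) and the cholesterol list (camera adjusted p = 0.0764) were lost, the latter also with a filter at 10 CPM (camera adjusted p = 0.17) and in the 5 libraries (camera adjusted p = 0.0528). With the kind term there were 8832 genes (7656 kept with their direction), the 8 libraries 5544 and the 5 libraries 7145. Library size only moved the median of all genes by -0.139 and called 2379 positive and 5063 negative.

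Across genes, which are not independent replicates, the chloroquine effect on 5-FU had almost no relation to that on vehicle (Pearson r = 0.0065, Spearman rho = 0.00599 over 19514 genes, r = 0.00214 with the kind term). Of 3620 genes called in both, 1860 moved the same way and 1760 the opposite way. The 5-FU effect with chloroquine was related to that without (r = 0.52, rho = 0.462, r = 0.501 with the kind term), with 5742 of 7056 genes moving the same way. The 2 comparisons of each pair share no library. The second correlation fell to 0.328 without vehicle 4 and to 0.23 without the filter on low counts, and the first ran from -0.0748 without combination 2 to 0.113 without 5-FU 2.

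**Figure D4:**
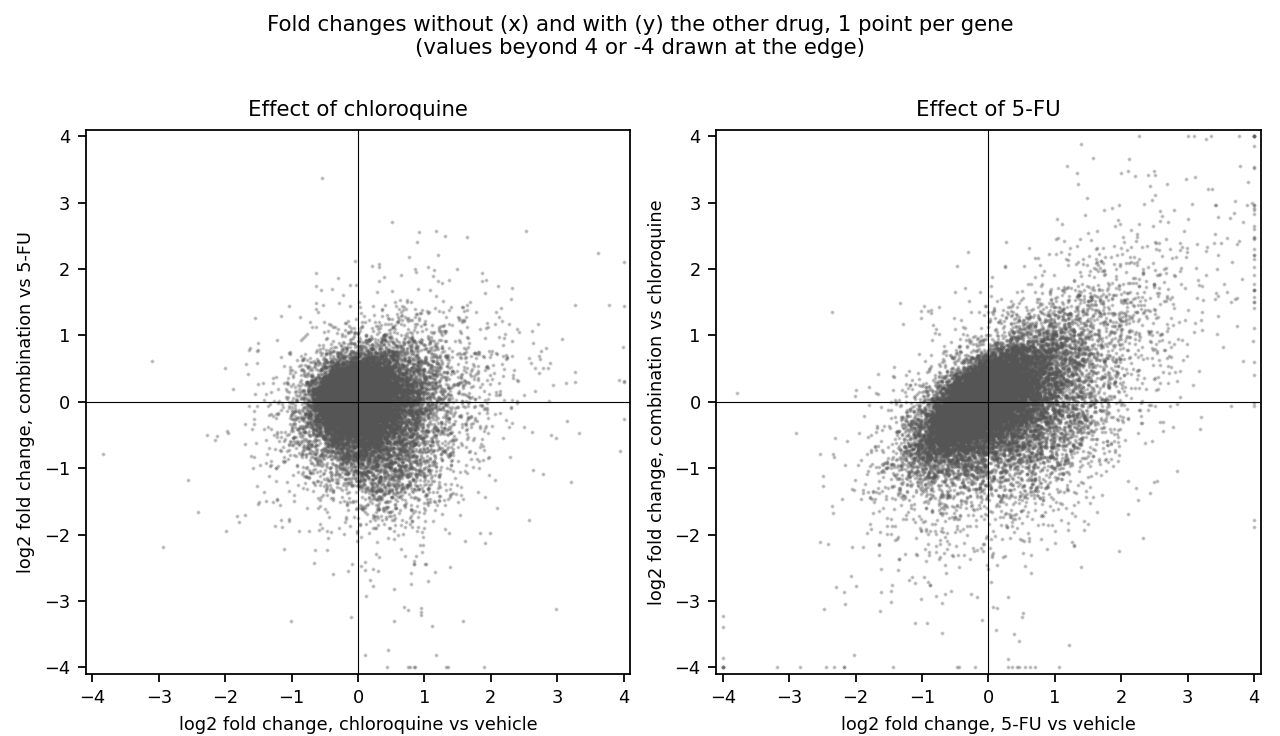
Log2 fold change of each of 19514 tested genes (points) without (x axis) and with (y axis) the other drug, for chloroquine (left) and 5-FU (right), values beyond 4 or -4 drawn at the edge. The points form a round cloud for chloroquine (r = 0.0065) and a rising one for 5-FU (r = 0.52).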

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

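The tests of mixed-in RNA or reads, of a drug effect on the kind of library, of library scaling by the genes lowered by each drug and all values by kind of library were chosen after the result was seen, and the tests of the genes below the additive level by simulation and by library size only were not.

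Among the vehicle libraries, 10 genes and measures, with 111 genes checked, had 1 library far from the other 3, and chance sets apart about 1 in 20. BBC3 in vehicle 2 was at 12.2 CPM against 13.5 in each of the others, and SQSTM1 there at 36.3 CPM against 33.1 to 33.5. In vehicle 1, NPM1 was at 1310 CPM against 1230 to 1240, POLA1 at 121 CPM against 134 to 136 and H2AC6 at 2.86 CPM against 3.82 to 3.94. In vehicle 4, MALAT1 was at 60.7 CPM against 66.6 to 67.7, INPP5D at 0.567 CPM against 0.385 to 0.399 and FN1 at 43.2 CPM against 36.7 to 37.1, and the summed fibroblast list was at 123 CPM against 10.8 to 14.3 and the summed leukocyte list at 13.8 CPM against 3.38 to 3.85.

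Vehicle 4 is 1 of the 5 libraries with transcripts of other tissues. In these, 1002 genes were higher and 943 lower by edgeR than in the other 8. Among the higher were 28.1% of 2055 processed pseudogenes against 2.43% of other genes. The kinds were set from residuals of the same values, so many calls were bound to come and are no independent support for them. The total share of processed pseudogenes was 6.048% in vehicle 4 against 5.978 to 6.102% in the other vehicle libraries. It exceeded that of all other libraries of the group only in 5-FU 2 (4.417% against 4.338% and 4.245%). Against a drug effect, 3 of 4 groups, vehicle among them, hold a library with at least 4 of the tissue lists below over 10 counts and one with at most 2; whether mixed-in reads are the whole difference stays open, since with 10 libraries parted by these lists alone 5.15% of 10493 genes at 10 CPM or more were called, 446 of 540 lower, close to the bound of 5%, although of 36 choices of as many libraries per group only the real one gave as many. RNA or reads of other samples may have entered vehicle 4, chloroquine 1 and 2 and 5-FU 2, where at least 4 of 6 tissue lists (connective tissue, red blood cells, muscle, exocrine gland, B cells and myeloid cells) had 2 or more genes over 10 counts, against at most 2 in the other 8. Combination 2 had 2 such lists, so the first form of this test (3 lists in each of the 5 libraries, at most 1 in the other 8) was not met, and whether mixing occurred there stays undecided, although 3 of its list genes exceeded 3 times their highest count in the 8 libraries without such transcripts. In 5-FU 2 the summed counts stood far above 5-FU 1 and 3 for exocrine gland (1175 against 69 and 95) and B cells (366 against 7 and 15). They were 953 against 628 and 624 for connective tissue, 79 against 46 and 72 for muscle and 32 against 26 and 19 for myeloid cells. For red blood cells they were lower, 53 against 69 and 76. Of the 29 list genes, 10 passed 10 counts in a library without such transcripts and 11 stand in another list, the genes shown (COL1A2, IGHM, AMY1A and S100A6) were picked after their values were seen, and reads of another species or a preparation batch were not tested.

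The chloroquine effect differed with and without 5-FU, by the interaction test of edgeR, in the genes named next. The log2 differences were -0.75 for CDKN1A, 0.41 for MDM2, -0.53 for BBC3, -1.45 for GDF15 and 0.34 for HMGCS1. The most negative of the rule were -4.22 for ONECUT3, -4.05 for PLXNB3, -3.35 for SLC34A3 and -3.12 for EPS8L2. Among genes named from the lists they were 1.53 for HSPA1B, -1.72 for PIDD1, 0.86 for NPM1, -2.07 for CHAC1, -1.95 for NEAT1 and -1.21 for FN1. The most positive of the rule were 2.49 for RN7SL4P, 2.37 for RN7SL1, 1.93 for RN7SL5P and 1.79 for MIR1244-3, all with near-identical copies and so uncertain. The calls of the RN7SL genes were lost without vehicle 1 (1.85, 1.86 and 1.25) or chloroquine 2 (2.30, 2.21 and 1.98). Those of RN7SL4P and RN7SL5P were lost with limma-voom (2.16 and 1.71) and in the 5 libraries (0.77 and 1.08). Those of RN7SL1 and RN7SL5P were lost without chloroquine 1 (2.16 and 1.70) or combination 3 (1.75 and 1.70). Lists passed the camera test with median differences of -0.22 (p53 targets), 0.25 (G2/M), 0.20 (cholesterol), -0.40 (ATF4), 0.79 (heat shock), 0.30 (ribosomal proteins), 0.47 (ribosome biogenesis), -0.30 (snoRNA hosts and nuclear RNAs), 0.41 (respiratory chain) and -0.77 (mitochondrial mRNAs), and of these heat shock alone kept its call with an estimated correlation.

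Of 2090 genes raised by each drug alone, 1541 lay below the sum of the single effects in the combination, CDKN1A among them, with 710 lower than with 5-FU, 76 higher and 978 above vehicle, and of 2118 lowered by each, 1628 lay above the sum. The 2090 compare with 1216 for independent lists of the same sizes. With the vehicle libraries split between the drugs, 1307 to 1357 genes were raised by each. Those fits had 2 vehicle libraries per drug, and the overlap of independent lists was not computed for them, so the 1216 is no baseline there. Simulated unchanged groups against shared vehicle libraries gave 0, which tells little, since few calls were possible without a change. Simulated additive combinations gave at most 1 gene raised by each drug and below the sum in 8 simulations. That argues against the spread of single genes in libraries shared between the comparisons. Each gene was drawn on its own, so deviations common to many genes of a shared library stay open. Library scaling as the whole cause is argued against, since it moves all genes one way while the 1628 lie the other way. The kind term gave 1739 such genes (1483 shared). That term takes up residual spread by construction, so it cannot decide on the kinds of library. Library size only gave 2449, but it moved the single effects up and the interaction down (medians by 0.0956, 0.192 and -0.139), which adds such genes, so the bound set on it beforehand decided nothing, and in the 8 libraries, with 1 chloroquine library, the number was 833. The labels name 0.1% DMSO for vehicle alone and do not say whether the drugs were given in it. Anything particular to the vehicle libraries would move both single effects one way and the interaction the other way. Here it cannot be told apart from a true lack of additivity, so the cause stays open.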

How the results depend on the processing

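The tests with a term for the kind of library, in the 8 or 5 libraries alone and with a block in 5-FU and the combination alone were chosen after the data were seen. No named gene or list result turned its direction and passed the test again under an alternative, and of all genes called with 5-FU 2 did with library size only and 1 in the 5 libraries. With library size only the G1/S list with 5-FU and the ribosomal protein list with chloroquine (this one also in the 5 libraries) changed sign as they lost their call. Counts of changed genes stayed within 1.5 times the reported ones under RLE and library size scaling, DESeq2, limma-voom, both filters, the groups compared alone (which allows no interaction), the block, the kind term and the 5 libraries. An absolute log2 fold change of at least 1 left 962, 2735, 2221, 970, 1777 and 1806 genes in the comparisons as ordered in the report and 251 beyond both drugs, by its construction. In the 8 libraries, with 1 chloroquine library, 4396 genes changed with chloroquine and 2012 lay beyond both drugs. The correlation of the chloroquine effects was 0.0663 in the 8 libraries. That of the 5-FU effects was 0.23 without the filter on low counts, 0.428 in the 5 libraries and 0.438 without combination 2; the cause was not tested. With an estimated correlation the p53 list of the interaction (median -0.22) no longer passed (camera adjusted p = 0.0865). In total 47 list results lost their call there, with 121 unaltered. Calls kept there were heat shock in the 3 comparisons against vehicle and the interaction, ribosome biogenesis against vehicle, NRF2 with chloroquine (camera adjusted p = 0.037) and the p53 targets wherever they passed except the interaction. Leaving out 1 library gave 6005 to 8720, 10761 to 11888, 9622 to 11551, 6110 to 7861, 8549 to 10625 and 6747 to 8237 changed genes and 2413 to 3286 beyond both drugs. It gave p53 medians of 0.23 to 0.29, 0.62 to 0.77, 0.92 to 0.96, 0.12 to 0.18, 0.49 to 0.56 and -0.23 to -0.16. Correlations ran from -0.0748, a change of sign (without combination 2), to 0.113 (without 5-FU 2) for chloroquine and from 0.328 (without vehicle 4) to 0.532 (without vehicle 1) for 5-FU. Of the named gene results, 49 lost their call in the 8 libraries, 47 in the 5, 22 with library size only, 2 with the kind term and 386 with the fold threshold. Outside 5-FU against the combination the replicate numbers were not taken to pair the libraries, since residual correlations passed 0.1 in 12, not all, of 18 same-numbered pairs (from -0.448 to 0.743), and 6 of the 12 libraries that share a number correlated best with their own. In 5-FU and the combination alone the block gave 6542 changed genes, 1 named gene result lost its call and no other gene or list call of that comparison changed. With the number as a block, 7584, 11392, 10336, 7469, 9972 and 7729 genes changed, 3036 lay beyond both drugs and the 5-FU correlation was 0.279. Under the block 10 named gene results (TYMS and MAP1LC3B with chloroquine among them) and the V-ATPase list of the combination (camera adjusted p = 0.0516) lost their call. It brought calls of 1 gene, BBC3 in the combination against chloroquine (0.27), and of 5 lists (camera adjusted p = 0.0384 pyrimidine and 0.0462 leukocyte with chloroquine, 0.0249 respiratory chain in the combination, 0.0459 histones against chloroquine and 0.0331 NF-kB in the interaction). Alternatives planned for normalized values were not run, since the table holds counts. Depth limits the genes of few counts, since in simulated data 3 of 40 interactions of genes under 1 CPM were called, against 113 of 160 of other genes.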

Other observations

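The test of reads lost between keratins and the naming of abundant genes outside the rule were chosen after the result was seen, and the tests on general epithelial genes and on other splits of the libraries were not.

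More tested genes of the basal squamous list rose than fell with each drug, although the list did not pass its test. The tested genes leave out KRT5, KRT14, KRT15 and TP63, which had at most 0, 4, 2 and 1 counts in the 8 libraries. In the basal squamous list 5 of 13 tested members rose, 2 fell and 6 did not pass with chloroquine (same counts adjusted over the list alone, camera adjusted p = 0.148), a list that passed in the 8 libraries (camera adjusted p = 0.0476). With 5-FU 8 rose and 3 fell (same counts adjusted over the list alone, camera adjusted p = 0.103). LAMA3, a laminin chain, rose with chloroquine by 0.83 ± 0.0697. Of the 6 squamous differentiation genes that could be tested, 5 rose in the combination against vehicle (same counts adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.179 with an estimated correlation), a call lost with library size only (camera adjusted p = 0.0623) and without the filter on low counts (camera adjusted p = 0.113). KRT10 was higher in the combination than with chloroquine by 1.11 ± 0.104 and than with 5-FU by 0.39 ± 0.1. In the mesenchymal list 5 of 13 tested members rose, 1 fell and 7 did not pass with 5-FU (same counts adjusted over the list alone, camera adjusted p = 0.413). In the combination 6 rose and 2 fell (same counts adjusted over the list alone, camera adjusted p = 0.171). SNAI1, a transcription factor of the epithelial to mesenchymal transition, was at 1.51 ± 0.28 in the combination and at 0.91 ± 0.288 with 5-FU, the latter call lost without 5-FU 1 (0.55) and in the 5 libraries (1.17). CDH2, encoding N-cadherin, fell with 5-FU (log2 -0.38 ± 0.0409) and in the combination (log2 -0.37 ± 0.0409), and FN1, encoding fibronectin, had an interaction of -1.21 ± 0.105.

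DNA repair genes went both ways. With 5-FU 12 of 25 tested members rose, 9 fell and 4 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.79). In the combination 13 of 25 tested members fell, 7 rose and 5 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.108), and the list passed without the filter on low counts (camera adjusted p = 0.0286). BRCA2 rose with chloroquine by 0.63 ± 0.116 and in the combination by 0.77 ± 0.115. Against 5-FU the combination had 10 falls and 1 rise (same counts adjusted over the list alone, camera adjusted p = 0.053), short of the threshold. It passed under 9 alternatives, with camera adjusted p = 0.0484 (RLE), 0.019 (library size only), 0.0485 (DESeq2), 0.0494 (limma-voom), 0.0304 (no filter), 0.0213 (filter at 10 CPM), 0.0465 (kind term), 0.0313 (the 5 libraries) and 0.0034 (without 5-FU 1). Among histones, whose genes are near-identical copies and uncertain one by one, 4 of 17 tested members fell, 2 rose and 11 did not pass with chloroquine (same counts adjusted over the list alone, camera adjusted p = 0.89). H1-4 fell with chloroquine (log2 -3.10 ± 0.381) and with 5-FU (log2 -2.36 ± 0.346), and H2AC6 rose in the combination by 1.66 ± 0.116. Against chloroquine the combination raised 8 histone genes and lowered 2 (9 up and 2 down adjusted over the list alone, camera adjusted p = 0.0662), a list that passed without chloroquine 1 (camera adjusted p = 0.0462), chloroquine 2 (camera adjusted p = 0.046) or combination 1 (camera adjusted p = 0.0282). It also passed without the filter and in the 8 or the 5 libraries (camera adjusted p = 0.0218, 0.0315 and 0.0489). The histone list with chloroquine had a median of 0.16 but a mean of -0.17 and a test pointing down, and the NRF2 list with 5-FU a median of -0.30, a mean of 0.098 and a test pointing down. Signs of median, mean and test also differed for the histone, ATF4 and snoRNA lists of the combination against 5-FU, the histone, pyrimidine and chaperone lists of the interaction, the mesenchymal list there, the autophagy and mesenchymal lists of the combination against chloroquine and the leukocyte lists of 5-FU and of the combination against vehicle, none of them past the test. Markers of other cell types, which differ between the kinds of library, did not pass the list test in the comparisons with vehicle. Of 5 fibroblast genes tested, 1 fell in the combination, a call not kept when adjusted over the list alone (camera adjusted p = 0.612). With the kind term 4 of them fell in the combination (median -2.17, camera adjusted p = 0.358) and 3 with 5-FU (median -1.64, camera adjusted p = 0.712), and 3 leukocyte genes fell in the combination and 2 rose (camera adjusted p = 0.877). Of 7 leukocyte genes 1 rose with chloroquine (same counts adjusted over the list alone, camera adjusted p = 0.192). It is a list that passed without chloroquine 3 (camera adjusted p = 0.0463). The 1 endothelial gene tested rose with 5-FU, with no list test.

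Squamous markers were near the floor in the 8 libraries without transcripts of other tissues. Of 29 squamous differentiation genes, 23 had 10 counts or fewer. Of 17 basal squamous genes, 4 (KRT5, KRT14, KRT15 and TP63) did, and DST (141 CPM) and LAMA3 (39 CPM) were among the others. VIM (772 ± 123), CDH2 (140 ± 10.9), NEFL (120 ± 27.4), INA (182 ± 53.1), NOG (2440 ± 1010), RSPO1 (1150 ± 498) and LIN28B (87.5 ± 10.3) were expressed (mean CPM ± SD). The SD here runs over the 8 libraries of all 4 treatments, so it includes treatment differences. Reads lost between near-identical keratins are argued against by 18 of 23 squamous differentiation genes that are not keratins and lay at 10 counts or fewer. A loss of squamous differentiation alone is argued against by 12 of 18 general epithelial genes with a mean of 1 CPM or less, among them ESRP1 (0.177 ± 0.184) and GRHL2 (0.0302 ± 0.0352), although KRT18 (50.9 ± 11) and CDH1 (2.05 ± 0.369) were measured. The same 12 genes are consistent with RNA of cells other than squamous epithelial cells, a hypothesis, and no reference profile of the line was used here. A squamous line in a mesenchymal state stays open.

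Other splits of the libraries into groups of the same sizes were counted for each comparison. Of 35 splits, 1, the real one, gave as many genes for chloroquine (7682, highest other 3352), for 5-FU (11759, highest other 6071) and for the combination (10801, highest other 5230) against vehicle. Chance is therefore unlikely there but not excluded. A share below 1 in 35 was not possible, and the 3 comparisons use the same vehicle libraries. The highest other split in each set 3 vehicle libraries against the fourth and the 3 treated ones, a structure of the samples that follows the treatment. For the combination against 5-FU (7517, highest other 0) and against chloroquine (9867, highest other 0), 10 splits are too few for a share under 0.05. Of the 10 for the combination against 5-FU, 4 part all 3 same-numbered pairs, the real one included, and 6 part fewer. Of 60 splits of the 13 libraries drawn at random, the real one included, 1 gave as many genes for the interaction (7791, highest other 3196) and 1 for genes beyond both drugs (3045, highest other 2), but these splits mix all 4 treatments and so test only whether the treatments matter at all, which leaves chance undecided for these 2 results.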
